A study of Homo sapiens with 4 samples.

How the data were processed

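RNA of LX-2 cells, a line of human stellate cells from liver, was measured on 4 one-colour Agilent gene expression arrays, 2 from cells kept for 6 days in medium of pH 7.2 and 2 from cells kept for 6 days in medium of pH 6.2. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, total RNA was extracted, amplified and labelled with Cy3 as cRNA. Per the file headers, the arrays were of design 028004 and were read with Agilent Feature Extraction 10.7.3.1, which the submitters' processing notes also name. The labels do not say whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

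The deposited scanner files hold intensity on a linear scale. Per the file headers, the processed intensity had been background-subtracted and detrended within each array by Feature Extraction, and had not been scaled between arrays. The deposited value table holds 1 log2 value per probe and array. Its 4 columns had a median of 3.44 each and their sorted values differed by at most 0.00285, so the authors' log2 values had the same distribution on each array. Set against log2 of the processed intensity of the same array, they correlated across probes at 0.998 or higher, with no centring of genes and no turned direction. How the authors reached this distribution is not given in the sources used here.

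Each array had 58717 spots that were not controls, for 42405 probes. Between 45.4% and 49.8% of these spots were well above background per array, no spot was saturated, and 535 to 659 spots per array carried an outlier flag and were left out. The 75th percentile of the signal lay between 63.1 and 69.8 intensity units. For pH 7.2 replicate 1 the scanner software's median coefficient of variation between repeated spots was 10.1% and out of its accepted range, against 6.03% to 6.71% on the other arrays. All 4 arrays came from 1 slide and 1 scan. The pH 7.2 arrays lay in row 1 of the slide and the pH 6.2 arrays in row 2, so slide row and pH cannot be told apart by design. The number of arrays limits the precision of every value, and an exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333.

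Log2 of the processed intensity was averaged over the spots of a probe, and each array's 75th percentile over all non-control probes was subtracted. Probes were named through the RefSeq accession in the scanner files, without its version, matched to a RefSeq gene table of assembly GRCh38.p14 that was used for names only. Of the 42405 probes, 25715 matched, for 19720 genes, and 16690 had no gene name here. A probe was tested if it was well above background on both arrays of at least 1 group and had a value on all 4 arrays, which left 20046 probes, 11555 of them named. For each gene the probe with the highest mean signal was used, which gave 9878 tested genes. Where other tested probes of a named gene disagreed with it, the text says so.

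The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided), with Benjamini-Hochberg adjustment over the 9878 genes and a threshold of 0.05. Log2 fold changes are pH 6.2 minus pH 7.2 and are given with the standard error of the fit. A probe not well above background on either array of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean log2 value against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Gene lists were compared with the other genes with limma's camera (preset correlation 0.01) and adjusted over the 35 lists with at least 5 measured genes. camera with an estimated correlation was run as an alternative. In that mode its test has only the 2 residual degrees of freedom of the fit, so a list could hardly pass after adjustment over 35 lists. Failing it does not show that correlation between genes undoes a call. fry was also run, which asks another question: whether a list's members move on balance one way, against no change and not against other genes. The 36 lists held 999 genes, of which 982 were on the array under a current symbol and 592 were measured. They covered stellate cell activation and matrix (myofibroblast markers, collagens, proteases and their inhibitors, quiescence, TGF-beta targets, actin and focal adhesion, epithelial and mesenchymal transition), acid handling (proton sensors, proton and bicarbonate transport, V-type ATPase, lysosome, autophagy), metabolism, stress responses, cell cycle, inflammation, ribosomal proteins, histones and markers of other liver cell types. The lists, the tests, the groups and the rule for named genes were set before the data were examined.

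The named genes are the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05 and a fitted change of at least 2-fold, leaving out placeholder symbols. To these come up to 4 members per list with the largest changes among those that passed, or up to 2 with the smallest p where none did. ACTA2, COL1A1, COL1A2, COL3A1, TGFB1, TIMP1, MMP2, SPP1, ASIC1, GPR4 and CA9 are named whatever their result. Some genes that this rule takes are not reported here.

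The alternatives were normexp background correction (offset 50), quantile scaling, centring on the median of tested genes, the authors' log2 values, no filter on dim probes, a filter on all 4 arrays, the mean over a gene's probes, each probe on its own, eBayes with trend and robust settings, the replicate number as a block, and leaving out each array. normexp had been planned on the mean spot signal and was run on the median spot signal, the raw signal in the files used here. Slide or scan as a block could not be fitted because all arrays shared 1 slide and 1 scan. Tested on 20 simulated sets with 200 changed genes among 9878, the fit for this comparison recovered 5.30% of genes changed 1.5-fold, 68.4% of those changed 2-fold and 96.9% of those changed 4-fold, and 5.19% of its calls were false. As 985 genes passed in the data, the adjusted threshold was stricter in the simulated sets, and these recovered shares may be too low for the data. The simulated noise was independent between genes and drawn from the variances of the same fit. The share of false calls there therefore does not carry over to correlated genes or to a difference between slide rows.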

Results

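Gene expression was measured in LX-2 cells, an established line of human hepatic stellate cells, the liver's main matrix-producing cells in fibrosis. The comparison asked how the cells' transcripts differed after 6 days in acidic medium (pH 6.2, n = 2 arrays) from those in medium of pH 7.2 (n = 2 arrays). Of 19720 named genes on the array, 9878 were measured well above background on both arrays of at least 1 group. Levels are log2 signal relative to each array's 75th percentile. Across genes, the 2 arrays of a group correlated at r = 0.996 for both pH 7.2 and pH 6.2, and arrays of different groups at r = 0.988 or higher. Genes are not independent replicates in these correlations. The median standard deviation between the 2 arrays of a group was 0.078 at pH 7.2 and 0.085 at pH 6.2 (log2). The first principal component held 69.6% of the variance and separated the groups.

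At pH 6.2 the cells had more transcript of TAGLN, MYL9 and ACTA2 and of 9 of 22 measured collagens and collagen-modifying enzymes, and less of decorin and of 15 of 18 replication-dependent histones. TAGLN, the actin-binding protein transgelin, rose 8.81-fold with the brighter of its 2 probes, from 2.33 ± 0.020 to 5.47 ± 0.043 (SD, n = 2). Its other probe had a log2 fold change of only 0.18. MYL9, a regulatory light chain of smooth muscle myosin, rose 7.69-fold, from 2.58 ± 0.031 to 5.52 ± 0.16 (SD, n = 2). ACTA2, alpha smooth muscle actin and the usual marker of stellate cell activation, rose 5.05-fold, from 7.72 ± 0.059 to 10.05 ± 0.049 (SD, n = 2). DCN, the small matrix proteoglycan decorin, was 6.34-fold lower, at 3.09 ± 0.084 against 5.75 ± 0.026 (SD, n = 2).

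In all, 985 genes passed the limma test at an adjusted p of 0.05, 535 higher and 450 lower at pH 6.2. Of these, 142 rose and 114 fell by at least 2-fold in the fit. Of these 256 genes, 39 were not well above background in 1 group with the probe used. For these 39 only a bound holds, and it can lie under 2-fold. For each of the 985 genes both pH 6.2 arrays lay on the same side of both pH 7.2 arrays, which passing the test all but requires. The groups lay apart in this way for 57.5% of all tested genes, where chance gives 33.3%. Genes are not independent in this share, and a difference between slide rows would raise it too. The count depended on the arrays and settings used: 0 genes passed in limma without pH 6.2 replicate 1 (2195 at an unadjusted p under 0.05), without pH 6.2 replicate 2 (2025) or with no filter on dim probes (2380). With the replicate number as a block 271 passed (174 higher, 97 lower), while 1682 passed without pH 7.2 replicate 2, 1358 without pH 7.2 replicate 1, 2057 with normexp background and 2149 with eBayes trend and robust settings. More genes were lower than higher with quantile scaling (561 higher, 583 lower), with the authors' log2 values (564 and 585), without pH 7.2 replicate 1 (675 and 683) and with a 75th percentile taken over detected probes (473 and 611), the last chosen after seeing the data.

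**Figure D1:**
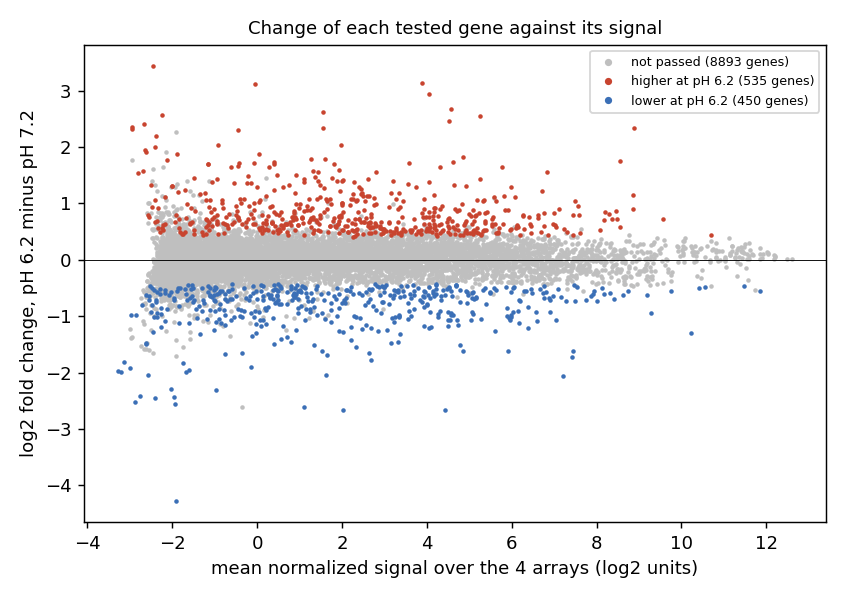
Log2 fold change (pH 6.2 minus pH 7.2) of each of the 9878 tested genes against its mean normalized log2 signal over the 4 arrays, 1 point per gene. The 535 genes higher and 450 genes lower at an adjusted p under 0.05 are coloured and occur over the whole range of signal.

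Among the 12 largest rises with a measured level in both groups, EDN1, the vasoconstrictor peptide endothelin-1, rose by 2.68 ± 0.090 (log2 ± SE). GADD45A, a growth arrest and DNA damage gene, rose by 2.55 ± 0.10. KCNMA1, the pore subunit of a calcium-activated potassium channel, rose by 2.61 ± 0.096, ERC2 by 3.13 ± 0.13 and GDAP1L1 by 2.34 ± 0.10. Of the other genes of this set, 4 were not well above background at pH 7.2 with the probe used and were at least 3.62-fold (SHANK2), 3.16-fold (HS6ST2), 2.20-fold (TPD52L1) and 1.77-fold (COXFA4L3) higher at pH 6.2. Another probe of TPD52L1 was well above background on a pH 7.2 array.

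The 12 largest falls included ITGBL1, with a log2 fold change of -2.66 ± 0.13 (SE), and NGEF, a guanine nucleotide exchange factor, with -2.60 ± 0.085. TNFAIP6, a secreted hyaluronan-binding protein, changed by -2.31 ± 0.11 and the metallothionein MT1H by -2.06 ± 0.11. Besides DCN, the other genes were not well above background at pH 6.2 and were lower there by at least 6.60-fold (CES4A), 3.56-fold (GRID1), 3.38-fold (CXXC4), 3.06-fold (HLA-DRA), 2.48-fold (LRRC17), 1.92-fold (ATIC) and 1.83-fold (RSL24D1). With normexp background the log2 fold changes shrank to 1.59 for ERC2, 1.93 for KCNMA1, 1.70 for GDAP1L1, -1.84 for NGEF and -0.88 for TNFAIP6. Those of the 11 genes given as bounds shrank to between 0.286 and 1.13 in size, below each bound. The adjusted p of the 24 genes with the largest rises and falls, not all of them named, lay between 0.00219 and 0.0330 in limma.

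Single genes rested mostly on 1 probe, and where there were more, they did not always show the same change. A second tested probe gave a log2 fold change of 0.18 for TAGLN, -0.09 for EDN1 and 0.39 for KCNMA1, whereas both probes of DCN fell, by 2.67 and 2.37. Over the 1284 genes with 2 tested probes, the log2 fold changes of the probes correlated across genes at r = 0.395, against at most 0.0717 in 100 shuffles. In a fit adjusted over all 20046 tested probes, named or not, both probes passed for 25 of these genes, always in the same direction. There 1 of the 2 passed for 85.

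Gene lists of activation, matrix and cytoskeleton were called higher by camera at its preset correlation. With an estimated correlation, where 2 residual degrees of freedom left little room to pass, none of these 4 lists passed (camera adjusted p = 0.759 for each). Their estimated correlations lay between 0.182 and 0.438, above the preset 0.01. These lists share members: TAGLN and COL1A1 are in 3 of them, and ACTA2, MYL9, FN1, COL1A2 and LOX in 2. Measured were 16 of 24 myofibroblast markers and 22 of 30 collagens and collagen-modifying enzymes. For TGF-beta targets this was 17 of 28 and for actin and focal adhesion genes 32 of 40. Of 16 measured myofibroblast markers, 8 rose, 1 fell and 7 did not pass (8 and 1 adjusted over the list alone), with a median log2 fold change of 0.38 (camera adjusted p = 0.00386). Besides TAGLN, MYL9 and ACTA2, the risers were FN1 (1.08), THY1 (0.84), COL1A1 (0.73), COL1A2 (0.59) and LOX (0.55). The member that fell was PDGFRA, a receptor for platelet-derived growth factor, by 1.25 on the log2 scale. Of 22 collagens and collagen-modifying enzymes, 9 rose and none fell (12 and 2 adjusted over the list alone; median 0.31, camera adjusted p = 0.00617), among them the prolyl hydroxylase P4HA3 (1.51), LOXL3 (1.39), COL8A1 (1.13) and COL5A1 (1.08, with 0.11 for its other probe). Of 17 TGF-beta target genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.43, camera adjusted p = 0.000587), including INHBA, which encodes an activin subunit (1.55). Of 32 actin cytoskeleton and focal adhesion genes 11 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.16, camera adjusted p = 0.000223), with PDLIM7 at 1.30 and, for its other probes, as low as 0.55.

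COL1A1 and COL1A2, the chains of type I collagen, stood at 8.84 ± 0.049 and 8.85 ± 0.061 at pH 6.2 against 8.11 ± 0.023 and 8.26 ± 0.022 at pH 7.2 (SD, n = 2), which is 1.66-fold and 1.51-fold higher (limma adjusted p = 0.0150 and 0.0254). TGFB1 had a log2 fold change of -0.14 ± 0.091 (SE) and did not pass (limma adjusted p = 0.402). COL3A1 was well above background on 1 of the 4 arrays, and TIMP1, MMP2 and SPP1 on 0, so these matrix genes were not tested. Of 10 measured proteases and inhibitors of the metalloproteinase and plasminogen systems none passed, also adjusted over the list alone (camera adjusted p = 0.618). ADAMTS2 had the smallest p (log2 fold change 0.38, with -0.32 for its other probe), followed by SERPINE2 (-0.32). Among 13 quiescence and retinoid genes 1 rose, ADIPOR1 (0.74, with 0.51 for its other probe), and 1 fell, STRA6 (-0.68, well above background on 1 of 2 pH 6.2 arrays), with 2 and 2 adjusted over the list alone (camera adjusted p = 0.403).

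**Figure D2:**
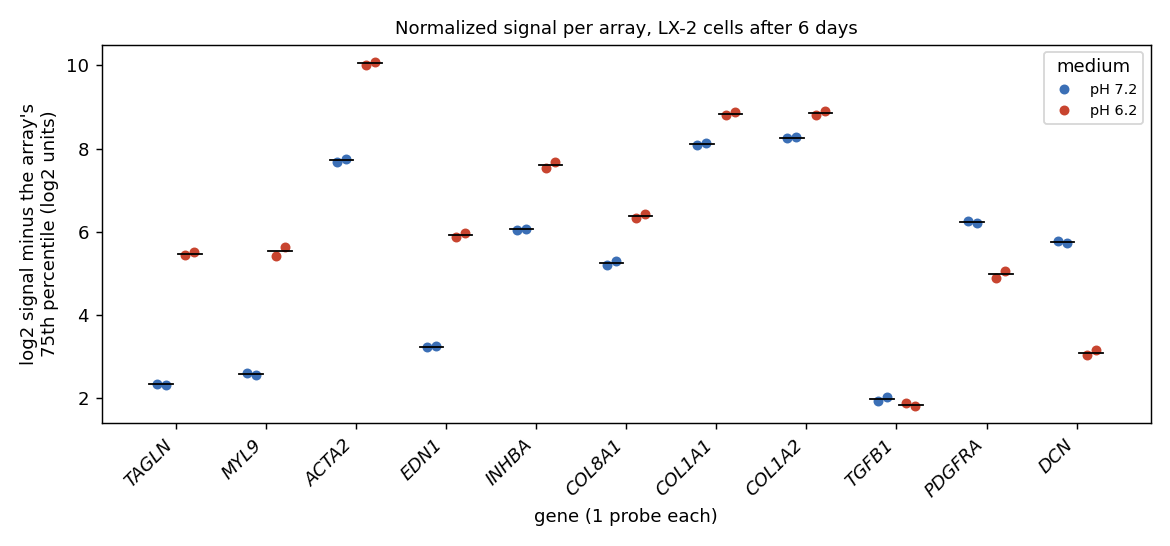
Normalized log2 signal (vertical axis, log2 units relative to the array's 75th percentile) of 11 genes on each array, with 2 points per group and a bar at the group mean. For TAGLN, MYL9 and ACTA2 both pH 6.2 arrays lie above both pH 7.2 arrays, for PDGFRA and DCN below, and for TGFB1 the group means of 1.97 and 1.84 did not pass the test.

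Replication-dependent histones fell almost throughout. Of 18 measured genes 15 fell and 0 rose (17 and 0 adjusted over the list alone), with a median log2 fold change of -0.92 (camera adjusted p = 9.88e-14, and adjusted p = 0.759 with an estimated correlation). H2BC3 changed by -1.21 ± 0.092 (SE), H2BC11 by -1.06 ± 0.086, H4C8 by -1.04 ± 0.089 and H3C2 by -0.99 ± 0.087. Near-identical histone copies can share a probe's signal, so single members are uncertain. Of the 43 mitotic genes listed, 25 were measured. Of these, 4 fell and 0 rose, the same numbers as adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.00411, and adjusted p = 0.759 with an estimated correlation). They were CCNA2 (-0.59), KIF23 (-0.57, with -0.32 for its other probe), ASPM (-0.57) and CDCA3 (-0.56). Of 22 DNA replication genes, MCM5 (-0.60, with -0.42 for its other probe) and MCM7 (-0.47, with -0.21 for its other probe) fell and UHRF1 (0.70) rose, with 3 lower and 1 higher adjusted over the list alone (median -0.05, camera adjusted p = 0.146). Among 20 p53 target genes 3 rose and 0 fell (5 and 0 adjusted over the list alone), GADD45A, TP53INP1 (0.76) and the cell cycle inhibitor CDKN1A (0.62), without the list passing (camera adjusted p = 0.416).

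Of the stress lists that follow, many members were not measured. The measured ones were 20 of 36 amino acid response genes, 15 of 30 hypoxia-inducible factor targets and 17 of 40 interferon-stimulated genes. The calls cover these members only. Of 20 genes of the amino acid response and ATF4 pathway 11 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.000382, and 0.759 with an estimated correlation). CHAC1, which degrades glutathione, rose by 1.56 ± 0.094 (SE) with 0.05 for its other probe, VLDLR by 1.42 and 1.48 with its 2 probes, ALDH1L2 by 1.10 and SLC3A2 by 1.30, though SLC3A2 (limma adjusted p = 0.0497) passed in only 5 of 15 alternative settings and stood at 0.60 with normexp background. Of 15 hypoxia-inducible factor targets 5 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 0.00905, and 0.759 with an estimated correlation). They were ERO1A (1.70), VEGFA (0.92 and 1.09 with its 2 probes), LOX (0.55), BNIP3L (0.53) and PGK1 (0.45). ERO1A stood at 1.002 with normexp background, and PGK1 passed in 6 of 15 alternative settings. Of 17 interferon-stimulated genes 4 rose, among them ISG15 (1.32), PSMB9 (0.92) and OAS3 (0.54), and 0 fell, the same count as adjusted over the list alone (median 0.19, camera adjusted p = 0.0108, and 0.759 with an estimated correlation). Without a filter on dim probes the hypoxia and interferon lists did not pass (camera adjusted p = 0.0842 and 0.264). The 60 cytosolic ribosomal protein genes had a median of 0.16 (camera adjusted p = 0.000191, and 0.759 with an estimated correlation), though none passed singly, also adjusted over the list alone. RPS29 (0.43, and 0.32 to 0.46 over its 3 probes) and RPL29 (0.34, with 0.41 for its other probe) had the smallest p. The 8 spike-in control probes well above background were also higher at pH 6.2, by 0.063 to 0.19, and fry, which tests a list against no change and not against other genes, did not call it (adjusted p = 0.178).

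**Figure D3:**
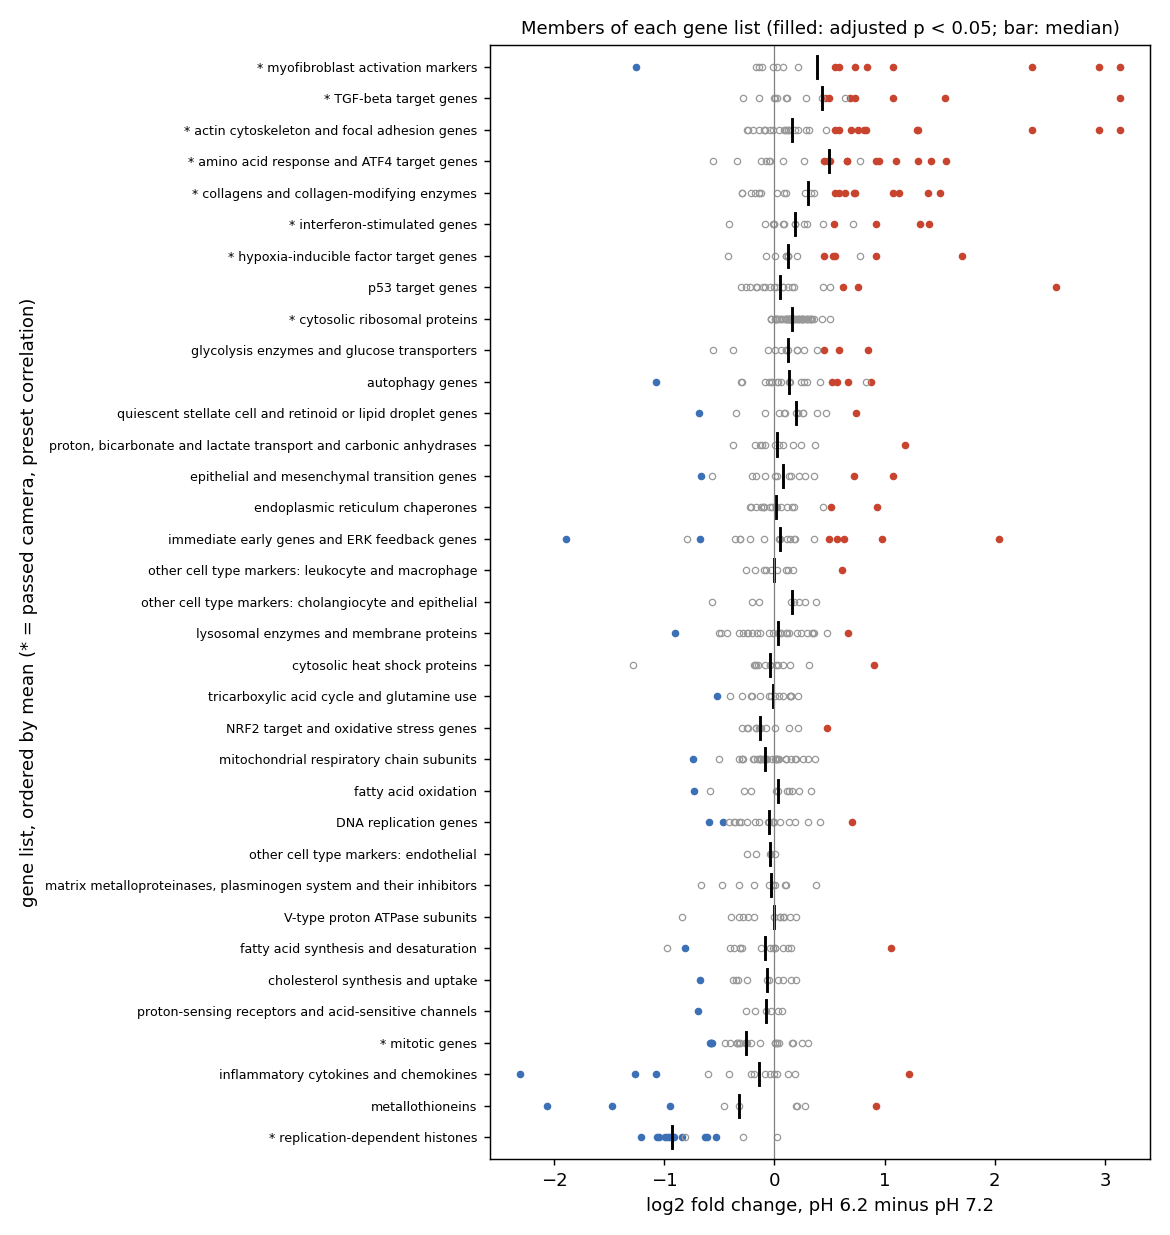
Log2 fold change (horizontal axis, pH 6.2 minus pH 7.2) of each measured member of the 35 tested gene lists, with 1 row per list, filled points for members with an adjusted p under 0.05 and a bar at the list's median. The median was -0.92 for the replication-dependent histones, 0.49 for the amino acid response genes and 0.43 for the TGF-beta targets.

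Genes that sense or move protons were tested where they could be measured. The fit recovered 5.30% of 1.5-fold changes in simulated sets with 200 changed genes. In the data 985 genes passed, which makes the adjusted threshold less strict, so this share may understate recovery. A gene that did not pass is still not shown to be unchanged. Of 7 measured proton-sensing receptors and acid-sensitive channels, the acid-sensing channel subunit ASIC3 fell by 0.69 on the log2 scale and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.307). These were TRPM7 (-0.26), KCNK3 (-0.18), ASIC2 (-0.08), GPR132 (0.07), ASIC4 (0.03) and PKD2L1 (-0.03). Of 12 transporters and carbonic anhydrases, CA11, a carbonic anhydrase-related protein without catalytic activity, rose by 1.18, and the others did not pass, also adjusted over the list alone (camera adjusted p = 0.959). Those 11 ranged from SLC4A2 (-0.38), a chloride and bicarbonate exchanger, to SLC4A7 (0.37), with SLC16A3, a lactate transporter, at -0.17, SLC4A3 at -0.13, SLC26A6 at -0.11, SLC4A11 at -0.08, SLC9A5 at 0.0033 (-0.090 for its other probe), SLC16A4 at 0.04, SLC9A7 at 0.08, CA14 at 0.17 and CA2 at 0.24. CA11 passed in 7 of 15 alternative settings, in none of 4 other scalings (limma adjusted p = 0.0567 to 0.0674), and ASIC3 in 11. Of those that did not pass here, SLC4A2 (limma adjusted p = 0.0719) passed in 5 and SLC4A7 (0.256) in 1. With normexp background the log2 fold changes of CA11 and ASIC3 were 0.36 and -0.20.

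None of 13 V-type proton ATPase subunits passed, also adjusted over the list alone (camera adjusted p = 0.264). The lowest were ATP6AP2 (-0.84, limma adjusted p = 0.0520, well above background on 1 of 2 pH 6.2 arrays), ATP6V1B2 (-0.40), ATP6V1G2 (-0.32) and ATP6V0B (-0.28). The highest was TCIRG1 (0.20), with ATP6V0C, ATP6V1H, ATP6V1G1, ATP6V0A1, ATP6V1F, ATP6V0E1, ATP6V1A and ATP6V0D1 between -0.24 and 0.14. ATP6V1B2 (limma adjusted p = 0.0680) passed in 7 of 15 alternative settings, among them the 4 other scalings (0.0364 to 0.0474), and ATP6V0B (0.123) in 2. ATP6AP2 passed in 3 of 14 and stood at -0.18 with normexp background. The genes ASIC1, GPR4 and CA9 were not well above background on any array. Nor were the sensors CASR, GPR65, HVCN1, KCNK2, P2RX4 and TRPC4, while TRPV1 and TRPV4 were on 2 arrays but not on both of a group. Of the transporters and carbonic anhydrases, BSG, CA3, CA5B, CA8, CA12, CA13, SLC16A1, SLC16A6, SLC16A7, SLC26A2, SLC4A4, SLC4A5, SLC4A8, SLC9A2, SLC9A3, SLC9A8 and SLC9A9 were not well above background on any array, and of the ATPase subunits ATP6AP1, ATP6V0A4, ATP6V0D2, ATP6V0E2, ATP6V1B1, ATP6V1C1, ATP6V1C2, ATP6V1D and ATP6V1E1 were not. Several of these are genes that every cell uses, so such a result does not show a gene to be unexpressed. Nor does a signal well above background show expression of the named gene, as probes of tissue-restricted genes also had one.

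The array also carried markers of other liver cell types. As probes of tissue-restricted genes were in part well above background, a measured marker is not thereby shown to be expressed. Neither the 8 epithelial and cholangiocyte markers nor the 5 endothelial ones held a member that passed, also adjusted over the list alone (camera adjusted p = 0.645 and 0.447). Their members with the smallest p were ELF3 (0.38) and ESRP1 (-0.57, well above background on 1 of 2 pH 6.2 arrays), and EMCN (-0.25) and ESAM (-0.17). Of 10 leukocyte and macrophage markers CD3E rose (0.61), also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.959). Of 20 hepatocyte markers 2 were measured, HP (-0.13) and SERPINA1 (-0.00174), and neither passed, also adjusted over the list alone.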

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

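Among the tests below, the spike-in test and the test of signal loss in 1 group were set before their results were seen, and all others were chosen only afterwards. Probes with no gene name were left out of the fits of the report and entered only the scaling and the alternative that tested every probe. Adjusted over the 8491 such probes tested, 13 passed the limma test between the pH groups, 9 higher and 4 lower at pH 6.2. Among them were 4 of 4575 probes for long intergenic RNA regions, all higher. The 2 of these that were well above background on all arrays target chromosome 16, 14398724 to 14425271, and chromosome 14, 21907285 to 21923485 (hg19), and rose by 2.11 ± 0.11 and 2.11 ± 0.14 (log2 ± SE). No annotation of that build was used here.

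The fall of the replication-dependent histones (median log2 fold change -0.92) was set against RNA handling and cell cycle. These histones' transcripts normally end without a poly(A) tail. The 20 measured genes of small RNA classes that also lack one had a median of 0.031 (bootstrap SE 0.088), with 11 higher and 9 lower. On these arrays this argues against a lower yield of such RNA as the whole cause. However, SNORA74A (-1.55), RPPH1 (-1.50) and SNORA74B (-0.61), named here after their values were seen, fell. Bootstrap SEs here come from resampling genes, so they measure the spread among genes and not between arrays or cultures. The 22 DNA replication genes, active in the same cell cycle phase, had a median of -0.053 (SE 0.079), above the bound of -0.46 set from the histones' median. Of these, 16 were lower and 6 higher, with MCM5 and MCM7 passing as lower and UHRF1 as higher. Another 22 genes of that list were not tested. The mitotic list was called lower (camera adjusted p = 0.00411 at the preset correlation). The bound takes replication genes and histones to fall alike with a smaller S phase share. This was not shown, so a smaller S phase share stays open. A direct effect of pH on histone transcripts or on their 3' ends also stays open and was not tested.

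The 256 genes changed at least 2-fold in the fit coincide with slide row. The 8 spike-in control probes well above background on all arrays were all higher at pH 6.2, by 0.063 to 0.19 (log2), under the bound of 0.5 set beforehand as evidence against slide row. That bound was wrong for so few probes: at the genes' share of such changes, 0.207 of 8 probes would be expected to change, so finding none decides nothing. The common shift of these probes reached the size of the median absolute log2 fold change of the tested genes, 0.176. Whether it reflects the scaling was not tested. Small changes and the balance of 535 higher to 450 lower genes may therefore depend on the scaling. Slide row and the medium pH cannot be told apart. No batch of culture, extraction or labelling is recorded, and 0 of the 2 slide rows held both groups, so such a batch, had there been one, and the medium pH cannot be told apart.

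Probes of genes that every cell uses were in part not well above background, while a share of the probes of tissue-restricted genes were. A tested probe existed for 125 of 167 genes of the ribosomal protein, respiratory chain, V-type ATPase and tricarboxylic acid cycle lists, against 131 of 354 olfactory receptors, 55 of 84 keratin-associated proteins and 9878 of all 19720 genes. Repeated spots of a probe correlated at 0.981 or higher across probes, which argues against misplaced spots, and the share of those 167 genes above background differed between groups by 1.80 percentage points, which argues against a loss of signal in 1 group. Probes that do not report the gene they are named for may contribute, since the changes of 2 probes of a gene correlated at only 0.395, a value between those that would decide. A gene not well above background here is therefore not shown to be unexpressed. Nor is a gene with a probe well above background thereby shown to be expressed, given the olfactory receptors and keratin-associated proteins with such probes.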

How the results depend on the processing

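The 75th percentile over detected probes and the test of every probe, named or not, were chosen after seeing the data. Signal over background limits the results: 50.1% of the genes were measured, and calls were lost when dim probes entered the fit. Of 985 genes changed at pH 6.2 (535 higher, 450 lower, 256 by at least 2-fold), the count stayed within 1.5 times under quantile scaling (1144, of which 561 higher and 583 lower), median centring (1056), the authors' log2 values (1149, of which 564 higher and 585 lower), a filter on all 4 arrays (1209), the mean over probes (862), each named probe on its own (1067) and the percentile over detected probes (1084, of which 473 higher and 611 lower). With every probe tested on its own, named or not, 724 of 20046 probes passed, and the probes of 506 of the 985 genes did. The count moved to 2057 with normexp (1116 higher, 941 lower, 116 at least 2-fold) and to 2149 with trend and robust settings (1225 higher, 924 lower). With no filter on dim probes 0 genes passed in limma, with 2380 at an unadjusted p under 0.05. The cause was not tested for these. With normexp the fold of 20 of the 96 named genes that passed shrank by over 1.5 times (TNFAIP6 from -2.31 to -0.88). Its offset of 50 compresses the changes of dim genes. With the replicate block, which leaves fewer degrees of freedom, 271 genes passed (174 higher, 97 lower), 266 of them among the 985, and 0 acid-sensing or pH regulation genes did. The deviations of same-numbered arrays correlated at -0.040 across genes, so the numbers were not shown to pair the samples.

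Leaving out each array, with the lone array assumed to vary like the other group, gave 0 to 1682 changed genes, 0 to 913 higher, 0 to 769 lower and 0 to 352 changed at least 2-fold. The 0 came without pH 6.2 replicate 1 (2195 genes at an unadjusted p under 0.05) and without pH 6.2 replicate 2 (2025), where the spread came from the pH 7.2 pair alone. The smallest adjusted p there was 0.0639 and 0.0796.

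With an estimated correlation (adjusted p = 0.759 for each of the 10) 0 lists passed (35 tested, the histones alone at an unadjusted p under 0.05, 0.0298), while 10 did at the preset one. With its 2 residual degrees of freedom this mode could hardly pass a list, so it does not decide whether correlation undoes the calls. The camera p rose also where the estimated correlation lay below the preset 0.01, as for the cholesterol list (-0.0359, unadjusted p from 0.0628 to 0.19). In the 15 other alternatives with camera, these 10 lists passed except the hypoxia and interferon lists with no filter (0.0842 and 0.264). fry, which tests a list against no change and not against other genes, called 9. Of the 10 lists, it did not call the ribosomal proteins (0.178) and mitotic genes (0.102), and it called the p53 targets (0.034). Leaving out pH 7.2 replicate 2 added the inflammatory list (adjusted p = 0.0119) and leaving out pH 7.2 replicate 1, or a variance trend in camera, the metallothioneins (0.0352 and 0.0472). Of the acid-sensing and pH regulation genes 2 passed, against 5 with normexp, 6 with trend and robust settings, 0 with no filter, and 0 to 4 leaving out each array. The median SD between replicates, 0.0818, was 0.0715 with quantile scaling, 0.156 with no filter and 0.0475 with normexp.

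Among the 96 named genes that passed, 5 passed in under 8 of 15 alternatives (SLC3A2, ATG16L2, LIF, PGK1 and CA11). Direction turned only in named genes that had not passed, but leaving out an array or adding the block cannot turn a gene whose groups lie apart. SERPINA1 turned to 0.059 with normexp and ranged from -0.030 to 0.026 leaving out each array, and ESAM ranged from -0.35 to 0.021. Slide or scan as a block could not be run, since all arrays shared both.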

Other observations

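Several groups not described above had members moving both ways without the list passing in camera. Of 21 immediate early and ERK feedback genes 5 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.717), with the phosphatase DUSP1 at 2.04 ± 0.094 (log2 fold change ± SE), MYC at 0.98, EGR3 at -1.89 ± 0.098 (-0.94 with normexp background) and ETV4 at -0.68. Of 14 inflammatory cytokines and chemokines 1 rose and 3 fell (1 and 4 adjusted over the list alone; 0.109). They were CSF1 (1.22, with 0.04 for a further probe), TNFAIP6 (-2.31), LIF (-1.26, with -0.10 for its other probe, and passing in 6 of 15 alternative settings) and CXCL12 (-1.07, with 1.18 for a further probe). Of 9 metallothioneins MT1H (-2.06), MT1E (-1.47) and MT1A (-0.94) fell and MT2A (0.92) rose (5 and 1 adjusted over the list alone; 0.146), and these near-identical genes can share probe signal. Of 14 genes of epithelial and mesenchymal transition FN1 (1.08) and ZEB2 (0.73 and 0.75 with its 2 probes) rose and TWIST1 (-0.66) fell, the same count as adjusted over the list alone (0.618). Of 21 autophagy genes 4 rose and 1 fell, again the same count adjusted over the list alone (0.191), with MAP1LC3A at 0.88, ATG16L2 at 0.67 (passing in 6 of 15 alternative settings), ATG13 at 0.57 and the initiating kinase ULK1 at -1.07. Of 27 lysosomal genes IDUA (0.67) rose and GRN (-0.90) fell (3 and 4 adjusted over the list alone; 0.717).

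Metabolic lists changed in few members. Of 15 glycolysis genes 3 rose, PFKL (0.85), PFKP (0.58) and PGK1 (0.45), and 0 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.109). Of 11 genes of cholesterol synthesis and uptake 0 rose and 1 fell, the same count adjusted over the list alone (0.146). Among 16 genes of fatty acid synthesis FADS3 (1.06) rose and AGPAT2 (-0.81) fell (1 and 1 adjusted over the list alone; 0.191), and among 11 of fatty acid oxidation ETFB (-0.73) fell (0 and 2 adjusted over the list alone; 0.618). UQCRH (-0.73) fell among 38 respiratory chain subunits (0 and 1 adjusted over the list alone; 0.264). DLST, not well above background at pH 6.2 and at least 1.35-fold lower there (a log2 fold change of 0.103 in size with normexp background, below this bound), fell among 16 genes of the tricarboxylic acid cycle (0 and 1 adjusted over the list alone; 0.618). Of 19 endoplasmic reticulum chaperones SEL1L (0.93) and PDIA4 (0.51) rose, the same count adjusted over the list alone (0.717). CRYAB (0.90) rose among 14 cytosolic heat shock proteins, also adjusted over the list alone (0.855), and SOD2 (0.48) among 13 NRF2 target and oxidative stress genes (0 adjusted over the list alone; 0.403). The median, the mean and the test differed in sign for the lysosomal genes (median 0.033, mean -0.020, camera direction down), fatty acid oxidation (0.033, -0.072, down) and the leukocyte markers (-0.0025, 0.040, up).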
